A study of Mus musculus with 11 samples.

How the data were processed

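Poly(A) RNA of mouse embryonic fibroblasts was sequenced in 11 libraries: 4 from cells with both copies of the β-actin gene Actb intact (WT), 4 from cells with 1 intact copy (Het) and 3 from cells with none (KO). Per the labels, the cells came from 10.5 day BALB/c embryos, and RNA was taken with TRI Reagent at 70% confluence and made into stranded mRNA libraries. A further KO library was left out by the submitters after quality control and is not among the deposited tables. The labels number the replicates but do not say whether each came from its own embryo or culture. The p-values thus measure the spread between these samples, which may leave out that between embryos.

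The deposited FPKM (fragments normalised to transcript length and library size) and the ends of its interval are estimates by Cufflinks 2.2.1, from reads placed with TopHat2 2.1.0 on the mouse genome GRCm38.p4, per the submitters' processing notes. The notes also name Cuffdiff without a version, and no comparison made with it is among the files. Each table lists 48892 loci with a gene ID, symbol and position. The deposited tables hold no read counts, so count models were not used.

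Loci were joined by ID and position. The WT 1 file had 31 symbols that had been turned into dates, and their names were taken from the other tables. Of symbols on a primary chromosome, 37342 were found in the RefSeq table of the same build on the same chromosome, which gave gene classes, and 33636 had a start or end within 10 bp. FPKM of loci sharing a symbol (1766 symbols), among them 2683 loci on unplaced or alternate sequences, were summed. That step treats the near-identical copies of major histocompatibility complex (MHC) genes on alternate sequences as 1 gene, and how reads were split among them is uncertain. Coordinates are given on GRCm38, counted from 1, for the locus on the primary chromosome. Loci with a failed estimate numbered at most 7 in a library.

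Values were scaled between libraries by the median of ratios over 13981 genes (factors 0.937 to 1.04), and genes with a scaled FPKM of at least 1 in at least 3 libraries were kept, 14948 in all. The log2 of FPKM plus a pseudocount of 1 was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, empirical Bayes moderation with a mean-variance trend, and all 11 libraries sharing the estimate of spread. Each comparison was adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05, and "rose" or "fell" is used for genes past it. All differences are on the log2(FPKM + 1) scale, which understates the change of low genes. The comparisons were KO against WT, Het against WT, KO against Het, and Het against the midpoint of KO and WT.

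Before the data were examined, 48 gene lists were fixed, covering actins, contractile and actin-binding proteins, chromatin complexes, the nuclear lamina, RNA polymerase I, angiogenesis, matrix, adhesion, Hox and patterning genes, growth control, interferon and MHC genes, signalling, imprinting, metabolism, stress and markers of other cell types. Lists with at least 5 tested members were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the 43 lists so tested, and again with the correlation estimated from the data. The list p-values below are camera's.

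The genes to name were set by a rule, also fixed in advance. It takes the 6 actin genes. It takes the 12 highest and 12 lowest genes of KO against WT, and the 8 highest and 8 lowest of Het against WT and of KO against Het, among genes past the threshold whose groups did not overlap, with a mean of at least 5 FPKM in the higher group. Predicted and clone names are excluded, as genes named Gm with digits, names ending in Rik, AC, AL, BC and RP clones, Mir, Snor and names with -ps or -rs. Symbols beginning with LOC are not among those patterns and so count. For the midpoint it takes 5 in each direction without the overlap condition, and for each list up to 4 members past the threshold with the largest change, or up to 2 with the highest FPKM where no member passed. Some genes that the rule takes are not reported here.

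FPKM carry no sequencing depth. Relative depth was estimated from the smallest steps between FPKM values of genes under 0.3 FPKM (at least 4507 genes per library), and lay between 60.7% (WT 3) and 125% (WT 4) of WT 1. The Cufflinks interval of genes between 50 and 100 FPKM had a median half-width of 6.42% to 8.58%, which covers estimation error within a library only.

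The fit was tested on simulated data, in which every group had the WT means and each of the 14948 genes its pooled spread. A seeded set of genes was then changed. In simulated KO against WT the fit recovered 55.2% of 67 genes changed 1.5-fold, 91.0% of 67 changed 2-fold and 98.5% of 66 changed 4-fold. Far fewer genes were changed than were called in the real data, and scaling and filtering were not simulated. Recovery in the real comparisons may therefore differ. The alternatives tried were other scalings, filters, pseudocounts and variance settings, library weights, the replicate number as a block, fits of only the groups compared, each library left out in turn, and, chosen after the data were seen, primary chromosomes only, protein-coding genes only, all chromosomes but X and Y, and a fit without the shallowest libraries, WT 3 and KO 1.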

Results

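Gene expression was measured by RNA sequencing in 11 libraries of mouse embryonic fibroblasts, 4 WT, 4 Het and 3 KO, to ask how gene programmes and chromatin-related expression differ with the number of intact Actb genes. Between 13885 and 14202 genes reached 1 FPKM in a library. Relative to WT 1, depth ranged from 60.7% in WT 3 to 125% in WT 4, and KO 1 had 65.6%. Libraries grouped by genotype. The first principal component (34.7% of the variance) set KO apart and the second (27.2%) set Het apart. Correlations over genes were 0.947 to 0.983 within groups and 0.907 to 0.949 between them.

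**Figure D1:**
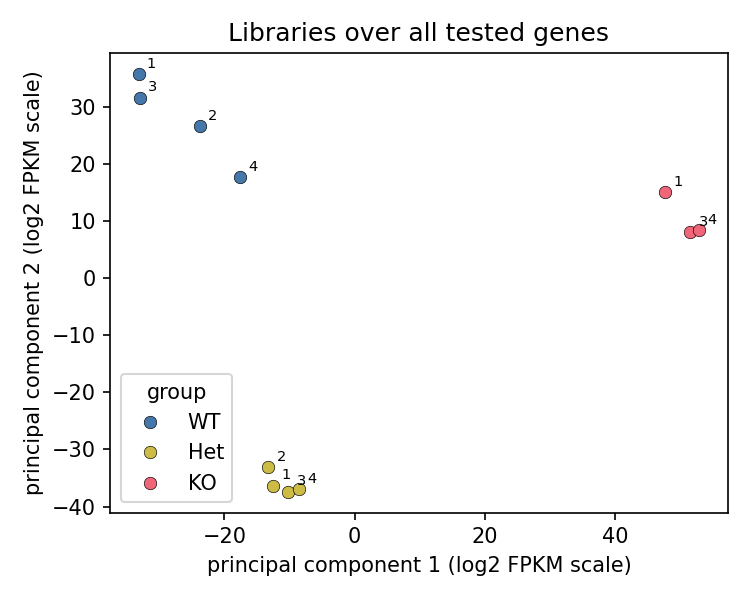
Principal components 1 and 2 of log2 FPKM over all tested genes, 1 point per library, labelled with the replicate number. The 3 genotype groups do not overlap, and the components hold 34.7% and 27.2% of the variance.

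The targeted gene was read first, as a check of the labels. Actb (gene13503, chromosome 5, 142903116 to 142906724), which encodes cytoplasmic β-actin, measured 1325 ± 199.6 FPKM in WT (SD, n = 4), 837 ± 24.0 in Het (SD, n = 4) and 45.8 ± 1.27 in KO (SD, n = 3). It fell in KO (log2 difference from WT -4.81, adjusted p = 8.48e-11) and in Het (-0.65, adjusted p = 0.00027). The 45.8 FPKM left in KO can hold reads shared with near-identical actin genes. Labels and Actb levels matched in all 11 libraries.

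**Figure D2:**
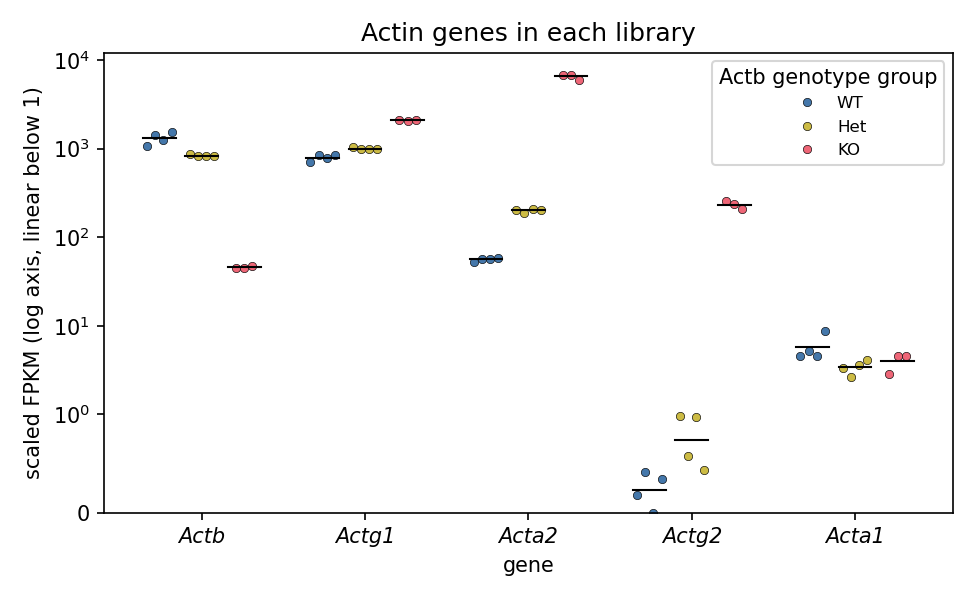
Scaled FPKM of the 5 tested actin genes in each library (log axis, linear below 1), with points for libraries and bars for group means. Actb is lowest in KO, whereas Actg1, Acta2 and Actg2 are highest there, with KO means of 2089, 6541 and 232 FPKM.

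The first comparison, KO against WT, asked what differs when no Actb gene is intact. The smooth muscle actins rose most. Acta2 (gene43115, chromosome 19, 34240336 to 34255585), the smooth muscle α-actin, measured 56.1 ± 2.80 FPKM in WT (SD, n = 4) and 6541 ± 447 in KO (SD, n = 3). Actg2, the enteric smooth muscle γ-actin, measured 0.233 ± 0.184 and 232 ± 23.5. The contractile genes Cnn1 (calponin), Myl9 (a myosin light chain) and Tagln (transgelin) rose with them, from 1.36 to 266, 8.40 to 505 and 43.9 to 835 FPKM. Among the genes that fell, Cthrc1, a secreted matrix protein (gene36356, chromosome 15, 39076851 to 39087121), went from 49.1 ± 3.21 to 0.0387 ± 0.0670 FPKM, and Pdpn, the membrane glycoprotein podoplanin, from 37.7 ± 4.72 to 0.114 ± 0.0754. Limma called 7042 of 14948 genes, 3481 higher and 3561 lower in KO, of which 724 and 407 changed at least 2-fold. Without scaling between libraries, 37.1% of 7401 called genes were higher, against 49.4% with it, so the balance of directions rests on the scaling.

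The actin list itself held 5 tested genes, of which 3 rose and 1 fell (3 and 1 adjusted over the list alone). Actg1, the cytoplasmic γ-actin, measured 791 ± 64.2 FPKM in WT (SD, n = 4) and 2089 ± 24.3 in KO (SD, n = 3; log2 difference 1.40, adjusted p = 8.38e-08). Acta1, the skeletal muscle actin, was not past the threshold (-0.40, adjusted p = 0.145), and Actc1 was too low to test. As a list the actins gave an adjusted p of 0.0755. Of the smooth muscle contractile genes and targets of serum response factor (SRF), 29 of 32 tested members rose (30 adjusted over the list alone), with a median log2 difference of 1.36 (adjusted p = 3.35e-18). Of the actin-binding and actin-nucleating proteins, 30 of 52 tested members rose and 6 fell (31 and 7 adjusted over the list alone), with a median of 0.49 (adjusted p = 2.08e-05). The leading members were Tmsb4x, a thymosin that binds actin monomers (2.28), Pls3, an actin bundler (1.52), Vasp, a promoter of filament growth (1.45), and Dstn, the depolymerising factor destrin (1.29). Integrins and focal adhesion genes rose too: 17 of 27 tested members rose and 2 fell (18 and 2 adjusted over the list alone), with Itga11 (3.17) and Itgb3 (2.22) at the top (adjusted p = 3.79e-05).

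Secreted factors and matrix genes were mostly higher in KO. Among secreted angiogenic factors, 23 of 33 tested members rose and 5 fell (24 and 5 adjusted over the list alone), with a median of 1.08 (adjusted p = 2.81e-07). That list mixes promoters and inhibitors of vessel growth, so its call gives no direction of angiogenesis. The leading genes were Ptn (3.90), Col18a1 (2.51), Sema3a (2.30) and Pgf (2.18). Of the matrix proteases and their inhibitors, 20 of 25 tested members rose and 2 fell (20 and 3 adjusted over the list alone) (adjusted p = 1.3e-08), among them Mmp23 (2.88), Serpine2 (2.69), Adamts2 (2.60) and Adamts5 (2.39). In the cytokine and chemokine list 14 of 20 tested members rose (16 adjusted over the list alone), led by the chemokine Ccl7 (3.55) and the prostaglandin synthase Ptgs2 (3.12), with an adjusted p of 5.56e-07. For fibrillar collagens and interstitial matrix, 22 of 37 tested members rose and 7 fell (23 and 7 adjusted over the list alone). Col3a1, Postn and Lox rose (4.06, 3.80 and 3.41) while the proteoglycan Bgn fell from 152 to 10.1 FPKM (-3.80). That list gave an adjusted p of 0.00109, but an adjusted p of 0.263 with an estimated correlation. Basement membrane genes (8 of 15 higher and 2 lower, or 8 and 2 adjusted over the list alone, adjusted p = 0.05) stood at the threshold without passing it. Endothelial markers went the other way, as 5 of 7 tested members fell (5 adjusted over the list alone), including Eng (-3.36), a co-receptor for TGF-β ligands, and Flt4 (-1.12), with adjusted p = 0.00479.

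Interferon and antigen presentation genes fell in KO. Of the interferon-stimulated genes, 1 of 34 tested members rose and 27 fell (1 and 29 adjusted over the list alone), with a median of -0.82, including Cxcl10 (-3.33), Ifi27 (-2.44), Isg15 (-2.33) and Gbp2 (-1.99). The test gave an adjusted p of 8.58e-11, and an adjusted p of 0.057 with an estimated correlation. Of the MHC class I and antigen presentation genes, 2 of 15 tested members rose and 12 fell (2 and 12 adjusted over the list alone) (median -1.51, adjusted p = 1.6e-05, and adjusted p = 0.057 with an estimated correlation). Psmb8, an immunoproteasome subunit, measured 31.0 ± 4.76 FPKM in WT (SD, n = 4) and 0.816 ± 0.0304 in KO (SD, n = 3). The class I heavy chain gene H2-D1 measured 92.2 ± 9.70 and 4.88 ± 0.377. Both are sums over 4 near-identical loci and uncertain in level, as are Cthrc1, Pdpn, Meg3, Rian and Cxcl5, which sum 2 loci each. Ulbp1, a ligand of the NKG2D receptor of natural killer cells, fell from 24.8 to 0.403 FPKM.

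Growth control and lipid synthesis differed as well. Among cell cycle genes, 1 of 49 tested members rose and 29 fell (1 and 29 adjusted over the list alone), with a median of -0.32. The mitotic genes Nusap1 (-0.99), Bub1 (-0.85) and Kif23 (-0.78) fell and the cyclin gene Ccne1 (1.27) rose (adjusted p = 4.97e-05, and adjusted p = 0.102 with an estimated correlation). Of the p53 targets and cell cycle inhibitors, 16 of 24 tested members rose and 5 fell (16 and 5 adjusted over the list alone) (adjusted p = 0.000645). They were led by Cdkn1a (2.82), which encodes the inhibitor p21, and the TNF receptor family genes Eda2r (2.19) and Fas (1.77). In the cholesterol and fatty acid synthesis list 2 of 34 tested members rose and 21 fell (2 and 21 adjusted over the list alone), with Acss2 (-1.49), Pmvk (-1.13) and Elovl6 (-1.03) lowest (adjusted p = 8.69e-05, and adjusted p = 0.057 with an estimated correlation). Oxidative phosphorylation subunits had a median of -0.08, where 3 of 74 tested members rose and 21 fell (3 and 21 adjusted over the list alone). Their adjusted p of 0.0137 became 0.42, an adjusted p with an estimated correlation, and it passed the threshold neither without KO 1 (adjusted p = 0.0593) nor without WT 4 (adjusted p = 0.0731).

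Hox clusters moved separately. HoxA genes were higher in KO, where 8 of 10 tested members rose (8 adjusted over the list alone) (adjusted p = 0.0029), with Hoxa9 at 1.74 and Hoxa10 at 1.11. All 3 tested HoxD genes rose (3 adjusted over the list alone), and Hoxd8 went from 0.0324 to 9.39 FPKM. HoxC genes were lower, where 5 of 8 tested members fell (6 adjusted over the list alone), with Hoxc4 (-1.68), Hoxc9 (-1.32) and Hoxc6 (-1.05) (adjusted p = 0.0115, and adjusted p = 0.057 with an estimated correlation). For HoxB genes, 6 of 9 tested members rose and 1 fell (7 and 1 adjusted over the list alone), Hoxb13 being the one that fell (-1.36). The adjusted p of 0.0294 was lost with an estimated correlation (adjusted p = 0.262) and without WT 1 (adjusted p = 0.0509). Limb and axial patterning factors were not called as a list (14 of 39 higher and 8 lower, or 14 and 8 adjusted over the list alone, adjusted p = 0.383), though Alx1 (3.65) and Msx2 (2.79) rose and Foxf1 (-1.97) fell. Of the imprinted genes, 15 of 28 tested members rose and 4 fell (15 and 5 adjusted over the list alone) (adjusted p = 0.00771, and adjusted p = 0.134 with protein-coding genes only). The long noncoding RNAs Meg3 and Rian of the Dlk1 domain went from 0.508 to 44.9 and 0.943 to 58.6 FPKM. Dlk1 (3.40) and Peg10 (2.63) rose with them.

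**Figure D3:**
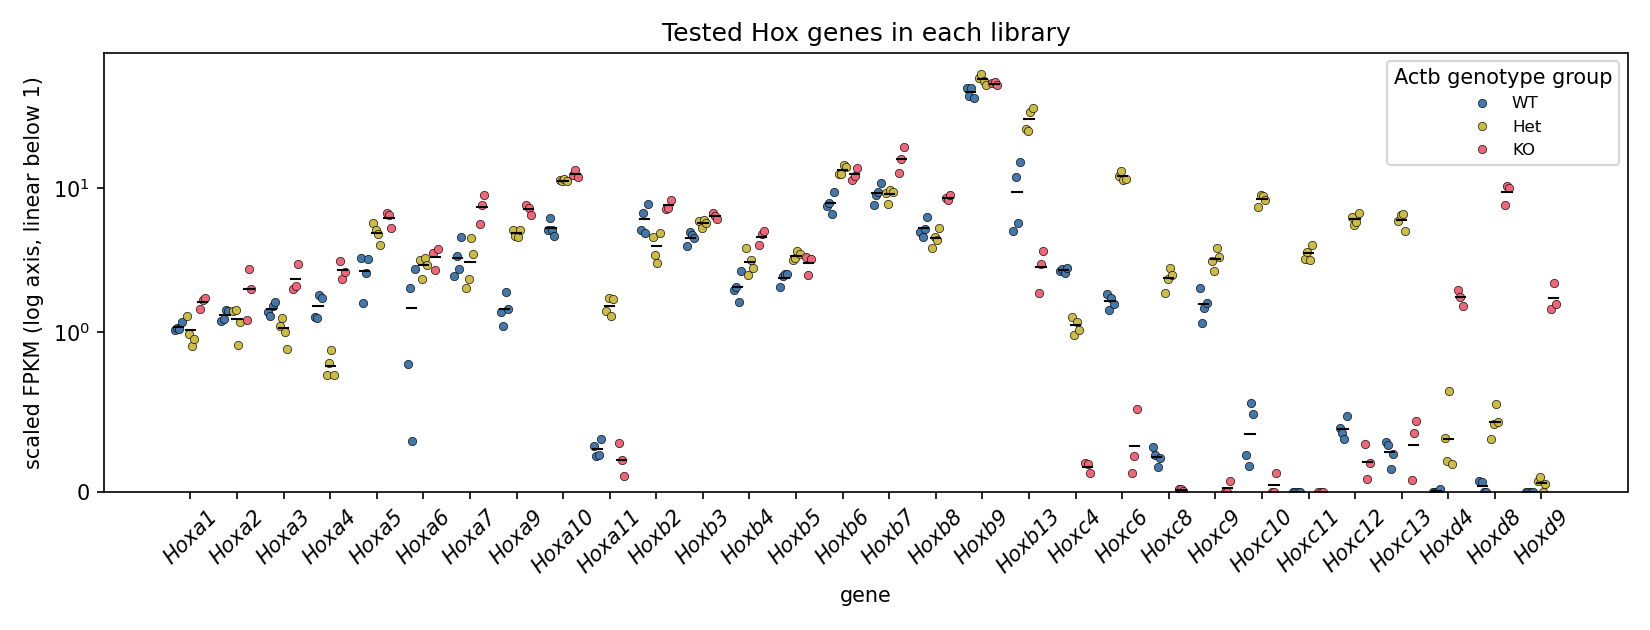
Scaled FPKM of tested Hox genes in each library (log axis, linear below 1), with points for libraries and bars for group means. Most HoxC genes sit highest in Het (Hoxc4 is highest in WT), with Hoxc6 at 1.64, 12.1 and 0.285 FPKM in WT, Het and KO, and Hoxd8 sits highest in KO.

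Lists of chromatin and nuclear proteins were not called in KO against WT. BAF and PBAF remodelling subunits had 6 of 25 higher and 9 lower, or 6 and 9 adjusted over the list alone, adjusted p = 0.6, with Brd9 (-0.82) and Pbrm1 (-0.75) lower and Arid1a (0.59) higher. INO80, SRCAP and TIP60 subunits had 1 of 29 higher and 9 lower, or 1 and 9 adjusted over the list alone, adjusted p = 0.116. Polycomb subunits had 12 of 30 higher and 4 lower, or 12 and 4 adjusted over the list alone, adjusted p = 0.0702. For H3K9 methylation, HP1 and DNA methylation genes the figures were 6 of 28 higher and 4 lower, or 5 and 4 adjusted over the list alone, adjusted p = 0.72, with the demethylase gene Kdm3a at 0.91 and the methyltransferase gene Dnmt3b at -0.62. The nuclear lamina and LINC complex had 6 of 19 higher and 3 lower, or 6 and 3 adjusted over the list alone, adjusted p = 0.289, where Syne2, a nesprin, rose from 4.84 to 10.7 FPKM. RNA polymerase I machinery had 2 of 20 higher and 6 lower, or 2 and 6 adjusted over the list alone, adjusted p = 0.239.

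Signalling lists passed the test at the preset correlation but not with an estimated one. This was so for Notch, ephrin and semaphorin genes (16 of 27 higher and 4 lower, or 16 and 5 adjusted over the list alone, adjusted p = 0.00628, adjusted p = 0.374 with an estimated correlation), where Notch3 (2.26) and Nrp1 (1.43) rose. TGF-β and BMP genes had 15 of 31 higher and 6 lower, or 15 and 7 adjusted over the list alone, adjusted p = 0.0136 (adjusted p = 0.0563 with an estimated correlation), with the BMP antagonist Grem1 at 2.24 and Bmp2 at -1.79. Growth factor receptors had 15 of 22 higher and 5 lower, or 15 and 5 adjusted over the list alone, adjusted p = 0.00648 (adjusted p = 0.0799 with an estimated correlation), with Pdgfrb at 1.85 and the collagen receptor gene Ddr2 at -3.09. Wnt genes were not called (14 of 28 higher and 10 lower, or 14 and 10 adjusted over the list alone, adjusted p = 0.675). Neither were glycolysis and hypoxia genes (16 of 35 higher and 8 lower, or 17 and 8 adjusted over the list alone, adjusted p = 0.0755). Cytosolic ribosomal proteins had 8 of 76 higher and 11 lower, or 7 and 9 adjusted over the list alone, adjusted p = 0.72. Immediate early genes had 6 of 19 higher and 4 lower, or 6 and 4 adjusted over the list alone, adjusted p = 0.424. Unfolded protein response genes (8 of 31 higher and 9 lower, or 9 and 10 adjusted over the list alone, adjusted p = 0.72) and heat shock proteins (4 of 17 higher and 5 lower, or 4 and 5 adjusted over the list alone, adjusted p = 0.73) were mixed. In these last lists the median and the mean differed in sign.

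Among markers of other cell types, the adipogenic and pluripotency lists were called higher at the preset correlation. Adipogenic markers had 6 of 10 higher and 1 lower, or 6 and 1 adjusted over the list alone, adjusted p = 0.00858, and adjusted p = 0.132 with an estimated correlation and 0.0629 without KO 4. The lipid droplet gene Plin4 went from 0.158 to 24.0 FPKM. Pluripotency and germline genes had 5 of 7 higher, or 5 adjusted over the list alone, adjusted p = 0.0137 (adjusted p = 0.0799 with an estimated correlation), with Hmga2 at 2.06. Osteogenic (3 of 5 higher, or 3 and 1 lower adjusted over the list alone, adjusted p = 0.116) and skeletal muscle markers (1 of 5 higher, or no member adjusted over the list alone, adjusted p = 0.861) were not called. The same held for neuronal and glial markers (4 of 10 higher and 5 lower, or 4 and 5 adjusted over the list alone, adjusted p = 0.933). Epithelial markers had 1 of 10 higher and 5 lower, or 1 and 5 adjusted over the list alone, adjusted p = 0.383, and pericyte and mesothelial markers 3 of 10 higher and 3 lower, or 3 and 3 adjusted over the list alone, adjusted p = 0.84. In the skeletal muscle and pericyte lists median and mean differed in sign. With under 5 tested members, chondrogenic (1 of 2 higher, or 1 adjusted over the list alone), cardiac (1 of 2 higher, or 1 adjusted over the list alone) and macrophage and blood cell markers (1 of 4 higher and 1 lower, or 1 and 1 adjusted over the list alone) had no list test. The cardiac troponin gene Tnnt2 rose by 3.35.

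The list calls of KO against WT that also held with an estimated correlation were the smooth muscle and SRF genes, actin-binding proteins, angiogenic factors, matrix proteases, integrins, cytokines, HoxA genes, p53 targets, imprinted genes and endothelial markers. The call of imprinted genes was lost among protein-coding genes alone (adjusted p = 0.134).

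Other genes named by the rule also differed between KO and WT. Cbr2, a carbonyl reductase, measured 7.47 FPKM in WT and 216 in KO, Fam111a 0.604 and 36.9, and Mgp, an inhibitor of matrix calcification, 0.618 and 32.6. Cyba, a subunit of NADPH oxidase, fell from 87.3 ± 43.8 (SD, n = 4) to 3.98 ± 0.317 (SD, n = 3). The surface protein gene Cd34 fell from 17.1 to 0.489 and the amino acid transporter gene Slc38a4 from 43.5 to 3.12. The uncharacterised gene LOC105243742 was listed at 0 in all WT and Het libraries and at 36.7, 21.9 and 26.5 FPKM in KO. LOC105245377 was listed at 0 in all KO libraries and lay between 8.94 and 21.7 FPKM in WT, and LOC105247112 fell from 62.9 to 3.85 FPKM.

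The comparison of Het with WT asked what differs when 1 of the Actb genes is intact. Some genes that WT cells hardly expressed were high in Het. Dcn, the proteoglycan decorin, measured 0.803 ± 0.279 FPKM in WT and 60.0 ± 8.72 in Het (SD, n = 4), and Col3a1 1.37 ± 0.126 and 71.7 ± 8.74. Gpnmb, a transmembrane glycoprotein (gene14518, chromosome 6, 49036518 to 49058182), went from 0.0567 ± 0.0453 to 52.8 ± 4.45. The neutrophil chemokine Cxcl5 went from 4.90 ± 0.606 to 174 ± 3.45, and Ptn, the growth factor pleiotrophin, from 9.21 ± 1.25 to 284 ± 18.1. Xist, the RNA that silences an X chromosome (gene45088, chromosome X, 103460373 to 103483233), measured 0.0503 ± 0.0105 in WT and 48.9 ± 3.45 in Het. Limma called 6546 of 14948 genes, 3243 higher and 3303 lower in Het, 456 and 240 of them at least 2-fold.

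The actins that rose in KO rose less in Het, and contractile genes moved both ways. Acta2 rose from 56.1 to 201 FPKM (1.82, adjusted p = 4.94e-09), and Actg1 rose by 0.35. Actg2, under 1 FPKM in these libraries, differed by 0.50, adjusted p = 0.014, which was not past the threshold with a pseudocount of 5 (0.13, adjusted p = 0.121). Acta1 had a difference of -0.57, adjusted p = 0.0354, which passed the threshold neither without WT 2 (adjusted p = 0.0557) or WT 4 (adjusted p = 0.0563) nor without Het 1, 2 or 3 (adjusted p = 0.0719, 0.0951 and 0.0614). The list of smooth muscle and SRF genes was not called (12 of 32 higher and 9 lower, or 12 and 9 adjusted over the list alone, adjusted p = 0.704), with Ctgf (47.8 to 7.21 FPKM), Cyr61 (-1.98) and Vcl (-0.92) lower. Actin-binding proteins were not called either (14 of 52 higher and 12 lower, or 15 and 12 adjusted over the list alone, adjusted p = 0.921), with a median of -0.06, opposite in sign to the mean. Tmsb4x rose (1.60) and the profilin gene Pfn2 fell (-1.36).

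HoxC genes mostly rose in Het and formed the list with the largest median, 2.25, among those tested here. In it 7 of 8 tested members rose and 1 fell (7 and 1 adjusted over the list alone), with Hoxc10 (2.80), Hoxc13 (2.50), Hoxc12 (2.35) and Hoxc6 (2.32) (adjusted p = 5.44e-05). Of the imprinted genes, 21 of 28 tested members rose and 3 fell (21 and 4 adjusted over the list alone), among them Rian (3.07), Meg3 (2.67), Dlk1 (2.55) and Mest (2.21) (adjusted p = 2.79e-05). Of the secreted angiogenic factors, 19 of 33 tested members rose and 3 fell (19 and 3 adjusted over the list alone), with Thbs2 (2.27) and Nov (2.21) next to Cxcl5 and Ptn (adjusted p = 0.000679). MHC class I and antigen presentation genes were lower, where 2 of 15 tested members rose and 11 fell (2 and 11 adjusted over the list alone) (adjusted p = 0.000679, and adjusted p = 0.248 with an estimated correlation). Psmb8 went from 31.0 to 4.79 FPKM, while H2-K1 differed by -1.39 when summed over its 3 loci and by 0.03 (adjusted p = 0.797) on the primary chromosome alone. Interferon-stimulated genes were not called (17 of 34 higher and 6 lower, or 18 and 8 adjusted over the list alone, adjusted p = 0.0652), with Ifit1 higher (3.62) and Gbp2 lower (-1.59).

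The calls of HoxC, imprinted and angiogenic genes held with an estimated correlation. Further lists passed in Het against WT only at the preset one. For growth factor receptors, 14 of 22 tested members rose and 3 fell (14 and 3 adjusted over the list alone), with Pdgfra at 2.14 (adjusted p = 0.000108, and adjusted p = 0.0501 with an estimated correlation). For p53 targets, 14 of 24 tested members rose and 4 fell (14 and 4 adjusted over the list alone), with Cdkn1a at 2.01 and Cdkn1c at 1.80 (adjusted p = 0.0105, and adjusted p = 0.0679 with an estimated correlation). In the cytokine list 12 of 20 tested members rose and 3 fell (12 and 3 adjusted over the list alone) (adjusted p = 0.0124, and adjusted p = 0.0702 with an estimated correlation). Among patterning factors 19 of 39 tested members rose and 9 fell (19 and 9 adjusted over the list alone), with Prrx1 at 2.33 and Foxd1 at -2.16 (adjusted p = 0.0222, and adjusted p = 0.308 with an estimated correlation). Cholesterol and fatty acid synthesis genes were higher, where 15 of 34 tested members rose and 4 fell (15 and 4 adjusted over the list alone) (adjusted p = 0.0222, adjusted p = 0.308 with an estimated correlation, and 0.0538 without WT 1). Fibrillar collagens and matrix had 18 of 37 higher and 10 lower, or 19 and 10 adjusted over the list alone, adjusted p = 0.0298, with adjusted p = 0.597 with an estimated correlation and 0.0724 without WT 1. Cell cycle genes had 6 of 49 higher and 17 lower, or 6 and 19 adjusted over the list alone, adjusted p = 0.0376, with adjusted p = 0.559 with an estimated correlation, 0.0628 without Het 4 and 0.0555 without WT 1.

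Among genes that fell in Het, Lrp2, the endocytic receptor megalin, measured 9.90 ± 0.899 FPKM in WT and 0.339 ± 0.0532 in Het (SD, n = 4). Sdpr, a caveolar protein, fell by 2.91 on the log2 scale, and the transcription factor gene Zic1 measured 5.38 ± 1.33 and 0.0169 ± 0.0215. Cthrc1 fell from 49.1 to 5.04 FPKM, Fam213b from 6.81 to 0.255, the creatine kinase gene Ckb from 11.8 to 0.906 and LOC100862431 from 28.9 to 3.27. Fam111a rose from 0.604 to 66.1, and LOC105247210 was listed at 0 in all WT libraries and lay between 24.5 and 84.2 FPKM in Het. The Polycomb list was not called (7 of 30 higher and 5 lower, or 7 and 5 adjusted over the list alone, adjusted p = 0.522), though the X-linked demethylase gene Kdm6a rose by 1.13. Kdm6a lay at 5.82 to 7.19 FPKM in WT, 14.2 to 16.4 in Het and 7.89 to 8.95 in KO. Only Het expressed Xist, so the rise of Kdm6a cannot be told apart from a difference in X chromosomes. BAF subunits had 5 of 25 higher and 8 lower, or 5 and 8 adjusted over the list alone, adjusted p = 0.649, with median and mean of different sign. INO80 subunits had 2 of 29 higher and 5 lower, or 2 and 5 adjusted over the list alone, adjusted p = 0.77. H3K9 and DNA methylation genes had 11 of 28 higher and 4 lower, or 11 and 4 adjusted over the list alone, adjusted p = 0.122. The list of Y-linked genes and Xist had 1 tested member, Xist, because Y-linked genes were near 0 in every library.

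The comparison of KO with Het separated cells with no intact Actb gene from cells with 1. Contractile genes were again far higher in KO: Actg2 by 7.08, adjusted p = 8.43e-11, Cnn1 by 6.27, Myl9 by 5.11, Acta2 by 5.02 and Tagln by 4.37 on the log2 scale. Some genes high in Het fell in KO to near the WT level or below, as Gpnmb (52.8 ± 4.45 FPKM in Het (SD, n = 4) and 0.0622 ± 0.0205 in KO (SD, n = 3)). So did Xist (48.9 and 0.0449), Dcn (60.0 and 1.18), Cd34 (66.1 and 0.489), Pdpn (65.4 and 0.114) and Efemp1, a fibulin (44.9 and 0.0514). Sdpr rose by 4.84 and the cartilage collagen gene Col2a1 from 0.417 to 25.6. Limma called 6603 of 14948 genes, 3291 higher and 3312 lower in KO, 517 and 441 of them at least 2-fold. Without scaling between libraries 36.5% of the called genes were higher, against 49.8% with it.

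Of the smooth muscle and SRF genes, 28 of 32 tested members rose (28 adjusted over the list alone), with a median of 1.51 (adjusted p = 2.92e-19). Actin-binding proteins (30 of 52 higher and 6 lower, or 30 and 8 adjusted over the list alone, adjusted p = 1.61e-05) were higher in KO, with Capg at 1.81. Integrins were too (15 of 27 higher and 3 lower, or 17 and 3 adjusted over the list alone, adjusted p = 0.000237), with Itga11 (3.16) and the fibronectin receptor gene Itga5 (2.14) among the leading members. For HoxC genes, all 8 of 8 tested members fell (8 adjusted over the list alone), with a median of -2.31 (adjusted p = 9.43e-09). Cholesterol and fatty acid synthesis genes fell as well: 2 of 34 tested members rose and 22 fell (2 and 23 adjusted over the list alone), among them Dhcr7 (-1.40), Lss (-1.38), Acss2 (-1.34) and Insig1 (-1.33) (adjusted p = 2.46e-07). Of the interferon-stimulated genes, 29 of 34 tested members fell (29 adjusted over the list alone), with Cxcl10 (-3.97), Ifit1 (-3.92), Isg15 (-3.53) and Ccl5 (-2.95) (adjusted p = 1.24e-14, and adjusted p = 0.0668 with an estimated correlation). MHC class I genes had 1 of 15 higher and 8 lower, or 1 and 10 adjusted over the list alone, adjusted p = 0.000607, and adjusted p = 0.186 with an estimated correlation.

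Of these, the SRF, actin-binding, integrin, HoxC and cholesterol lists held with an estimated correlation. Other lists called in KO against Het did not. Notch, ephrin and semaphorin genes rose in KO (14 of 27 higher, or 14 and 1 lower adjusted over the list alone, adjusted p = 0.000607, and adjusted p = 0.398 with an estimated correlation). Matrix proteases rose too (15 of 25 higher and 5 lower, or 15 and 5 adjusted over the list alone, adjusted p = 0.000607, and adjusted p = 0.165 with an estimated correlation). Cytokines had 12 of 20 higher and 4 lower, or 12 and 4 adjusted over the list alone, adjusted p = 0.015 (adjusted p = 0.0872 with an estimated correlation). Basement membrane genes had 9 of 15 higher and 2 lower, or 9 and 2 adjusted over the list alone, adjusted p = 0.0135 (adjusted p = 0.529 with an estimated correlation). Cell cycle genes were lower (6 of 49 higher and 21 lower, or 6 and 22 adjusted over the list alone, adjusted p = 0.0138, and adjusted p = 0.4 with an estimated correlation). Endothelial markers had 4 of 7 lower, or 4 adjusted over the list alone, adjusted p = 0.0347, with Eng at -3.48. The adjusted p was 0.161 with an estimated correlation and 0.0533 without KO 1. Mdk, the growth factor midkine, fell by 3.76. LOC105247112 fell from 115 to 3.85 FPKM. LOC105243841 differed by -5.35, adjusted p = 0.0293. It was not past the threshold when Het 1, 2 or 3 (adjusted p = 0.0557, 0.0625 and 0.0559) or KO 1 or 4 (adjusted p = 0.109 and 0.111) was left out.

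**Figure D4:**
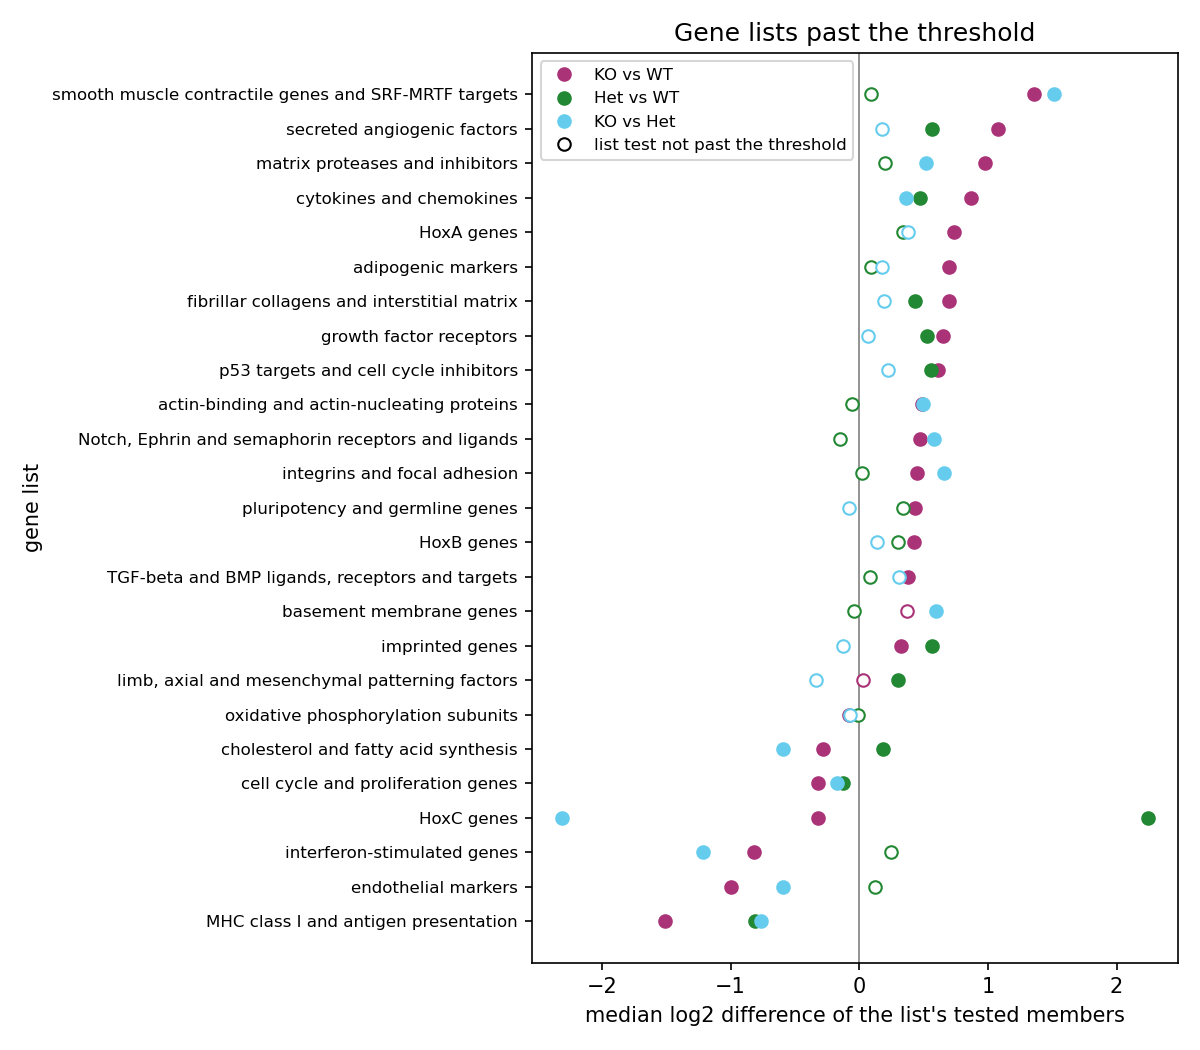
Median log2 difference of each gene list past the threshold in any of the 3 comparisons, 1 point per comparison, filled where the camera test passed at the preset correlation. HoxC genes have medians of -0.32, 2.25 and -2.31 in KO against WT, Het against WT and KO against Het.

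The last comparison asked whether Het lay at the midpoint of KO and WT on the log2 scale. A level proportional to the number of intact genes would lie above that midpoint, so a departure upward does not by itself depart from proportion. Actb itself lay above the midpoint by 1.76 (adjusted p = 6.8e-08), and Acta2 and Actg2 below it, by -1.60 and -3.29. Smooth muscle and SRF genes lay mostly below, where 24 of 32 were lower and 2 higher (24 and 2 adjusted over the list alone; adjusted p = 3.87e-13). So did actin-binding proteins (8 of 52 higher and 28 lower, or 8 and 29 adjusted over the list alone, adjusted p = 0.00673). HoxC genes lay above (7 of 8 higher, or 7 adjusted over the list alone, adjusted p = 7.52e-08). Gpnmb (5.66), Xist (5.57) and Dcn (4.94) lay far above it, and Sdpr (-3.88) and Ctgf (-3.12) far below. LOC105247210 (4.46) and LOC105243841 lay above too, the latter by 4.75, adjusted p = 0.0212, which became 0.0552 without Het 2. In all, 6582 genes departed from the midpoint, 3177 above and 3405 below, 542 of them by at least 1 on the log2 scale. Which side held more depended on the scaling: 48.3% of the called genes lay above with it and 57.7% without.

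The SRF, actin-binding and HoxC lists held at the midpoint with an estimated correlation, although the actin-binding call was lost with quantile normalization (adjusted p = 0.0855). Interferon-stimulated genes lay above it at the preset correlation (25 of 34 higher and 3 lower, or 26 and 3 adjusted over the list alone, adjusted p = 1.51e-09). They had adjusted p = 0.137 with an estimated correlation. Cholesterol synthesis genes lay above as well (23 of 34 higher and 3 lower, or 23 and 3 adjusted over the list alone, adjusted p = 2.35e-06, and adjusted p = 0.0591 with an estimated correlation). So did growth factor receptors (12 of 22 higher and 3 lower, or 12 and 3 adjusted over the list alone, adjusted p = 0.00853, and adjusted p = 0.137 with an estimated correlation). Imprinted genes had 16 of 28 higher and 6 lower, or 19 and 6 adjusted over the list alone, adjusted p = 0.0106 (adjusted p = 0.0591 with an estimated correlation). Integrins lay below (3 of 27 higher and 15 lower, or 4 and 16 adjusted over the list alone, adjusted p = 0.00952, and adjusted p = 0.0591 with an estimated correlation). Below it also were Notch, ephrin and semaphorin genes (2 of 27 higher and 15 lower, or 2 and 15 adjusted over the list alone, adjusted p = 0.0124, and adjusted p = 0.535 with an estimated correlation). Of the 7042 genes called in KO against WT, 3882 departed from the midpoint and 3160 did not. Among the 1131 that changed at least 2-fold in KO, the Het difference was a median 0.363 of the KO difference. In 868 genes Het lay between KO and WT and differed from both in the direction of KO, and in 2853 it lay beyond both, above in 1444 and below in 1409. Each count requires 2 calls that share the Het libraries, and genes with Het in between have smaller steps to pass. The sizes of the counts therefore cannot be compared directly.

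Genes called against WT overlapped between KO and Het: 3326 were called in both in the same direction, 1622 higher and 1704 lower, and 728 in opposite directions. Cthrc1, Psmb8, Meg3, Rian and Col3a1 were among the former. Independent lists of these sizes would share 755 higher and 787 lower genes, a figure that leaves out the shared WT libraries. Simulated unchanged groups against the same WT libraries shared at most 1 gene in any of 100 draws. With no gene changed, hardly any can be called there, so this is no chance level for lists of the real sizes. With the WT libraries split between the comparisons, 2263 to 3069 genes were shared in the same direction over the 6 splits and 441 to 1229 in opposite ones. The correlation of the log2 differences across genes, which are not independent replicates, was 0.45 (simulated 0.46), with a covariance of 0.159 (simulated 0.0207) and of 0.102 to 0.144 when the WT libraries were split.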

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

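The tests of copy number, depth, population, MHC haplotype, primary-chromosome rows, MHC members with 1 locus and interferon response were chosen after their results had been seen. The splits of the libraries, the share of MHC reads on primary loci and the tests of the third component were set beforehand. The copy-number test replaced an earlier test on the share of genes with Het in the middle, whose limit was written after related counts had been seen. The population rule was rewritten after Xist was seen, the depth verdict was made stricter after its correlation was seen, and the share of MHC reads was set aside as undecided after its values were seen.

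In groups of 4, a library lay far from the others of its group for 12 of 283 measures, where chance gives about 1 in 20. Acta1 was 8.69 FPKM in WT 4 and 4.49 to 5.19 FPKM in the others of its group. Fas was 19.2 FPKM in WT 1 and 15.1 to 15.4 FPKM in the others of its group. Foxd1 was 13.7 FPKM in WT 4 and 9.85 to 10.2 FPKM in the others of its group. Insig1 was 41.6 FPKM in Het 4 and 44.8 to 45.5 FPKM in the others of its group. LOC105247112 was 174 FPKM in Het 1 and 92.9 to 97.6 FPKM in the others of its group. Lrp2 was 8.56 FPKM in WT 4 and 10.3 to 10.4 FPKM in the others of its group. Mest was 19.12 FPKM in Het 3 and 14.2 to 14.8 FPKM in the others of its group. Pdgfra was 0.160 FPKM in WT 2 and 0.226 to 0.234 FPKM in the others of its group. Pdpn was 62.5 FPKM in Het 4 and 66.1 to 66.7 FPKM in the others of its group. Postn was 0.445 FPKM in WT 3 and 0.106 to 0.139 FPKM in the others of its group. Tmsb4x was 516 FPKM in Het 3 and 607 to 619 FPKM in the others of its group. The interval half-width of genes between 50 and 100 FPKM was 7.54% in Het 1 and 6.53 to 6.68% in the others of its group.

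The real arrangement of the libraries called more genes than any other split tried. The real split counts itself, so 1 of 35 (1 of 100 for the midpoint) is the smallest share the test could give. It cannot tell genotype from other differences between the cells of the groups. For KO against WT, 1 of 35 splits called as many genes as the real one (7042), and the highest other called 5373. For Het against WT and KO against Het the figures were 1 of 35 each, with 6546 and 6603 genes against at most 1 and 3. For the departure from the midpoint it was 1 of 100, with 6582 against 2983. The split with 5373 genes kept KO 1, 3 and 4 together and moved only WT 4 to their side, so it still follows genotype.

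The groups differ in many genes, and Het lies beyond both other groups in many of them. A response that only rises or only falls with the number of intact Actb genes is argued against as the whole cause by the 2853 genes in which Het passed the threshold against both other groups in the same direction. Het had the middle mean in 38.1% of the 9486 genes that differed over the groups, and in 46.6% of the 1758 with a range of at least 1 on the log2 scale. WT had it in 33.8% and 32.8% of these genes, and KO in 28.0% and 20.6%. The lower depth of WT 3 and KO 1 is argued against too, since 5473 genes were called in KO against WT without them. It remains open whether the cell populations differ for reasons other than Actb: Xist was at least 43.99 FPKM in every Het library and near 0 elsewhere, and a difference that follows genotype in this way cannot be told apart from genotype with the libraries at hand.

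MHC class I and antigen presentation genes were lower in KO and in Het than in WT at the preset correlation, and neither list call held with an estimated one. The 4 tested list members outside chromosome 17 have 1 locus each, and 3 of them fell in KO and 3 in Het (2 in 7 of the 11 fits without 1 library), which argues against reads spread over alternate MHC sequences as the whole cause, and in KO against differences in the MHC region of chromosome 17 as the whole cause. For the 11 members with several loci, such a spread cannot be told apart from a change in expression. In WT the share of FPKM on the primary locus of 8 of them lay within 5 percentage points of an even split, so 2 measures could not decide. Their median on primary chromosomes alone was -1.17 in KO and -0.51 in Het, against -2.01 and -1.02 with loci summed. The log2(FPKM + 1) scale understates the change of low values, and a single locus holds less FPKM than the sum. The smaller medians are therefore not by themselves a sign of read placement. The primary share of H2-D1 was nearly the same in WT and KO. Its KO difference was still -3.43 on the primary chromosome and -3.98 with loci summed. The share differed between Het and WT by more than 20 percentage points in 0 of 11 and by under 10 in 9. H2-K1, not near an even split, came close to 20. Its share was 11.4 ± 0.457% in WT and 31.3 ± 1.04% in Het (SD, n = 4), so the placement of its reads differed. That of H2-T23 was 70.1 ± 2.42% and 81.8 ± 1.54%. A weaker interferon response over the whole list is argued against in Het, where 6 interferon-stimulated genes were lower and 17 higher. Gbp2 was among the 6, so a weaker response of part of the list stays open there. In KO a weaker response stays open, as 27 were lower and 1 higher (adjusted p = 8.58e-11, and 0.057 with an estimated correlation). Reads on alternate sequences may account for part of the change in Het, where H2-K1 was past the threshold with loci summed (adjusted p = 4.13e-07) and not on primary chromosomes (adjusted p = 0.797), and a haplotype difference for part of that in chromosome 17 genes such as H2-D1.

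Libraries of the same group spread along the third principal component, and Col1a1, named after its values were seen, ranged from 84.1 (WT 1) to 324 FPKM (WT 4). Replicate 4 had the lowest value of its group on that component (-43.4 in WT, -9.50 in Het and -15.5 in KO). Whether a factor shared by replicate number accounts for the spread was not tested. Depth stays open as an explanation. An axis made by depth should fade among well-expressed genes. For the 2116 genes of at least 50 FPKM, the leading component that best matched the axis of all genes was taken, with group means removed. It followed that axis with Pearson's r = 0.879 over 11 libraries (permutation p = 0.00055, adjusted 0.00087, rho = 0.764, permutation p = 0.00847), though r was 0.787 without 1 library and 0.645 without the 2 farthest. Choosing the component by its match raises r, and the permutations do not allow for that choice. These genes are also part of the axis of all genes, so the result cannot decide. Against the axis of the genes below 50 FPKM alone, chosen by its match in the same way, r was 0.880 (permutation p = 0.00058, adjusted 0.00087, rho = 0.764, permutation p = 0.00845, and r = 0.631 without the 2 farthest). Relative depth itself, also with group means removed, still went with the axis over all genes (r = -0.71, permutation p = 0.0132, adjusted 0.0132, rho = -0.83, permutation p = 0.00265, and r = -0.78 without the 2 farthest), the last of the 3 correlations computed. For all 3 the permutations shuffled values freely over the 11 libraries after group means were removed, so their p-values may be too low. A difference in growth state may contribute, since cell cycle genes followed the axis with a median correlation of 0.734, above 98.5% of 10000 random lists matched on expression, and collagens went the other way (-0.27, percentile 4.43). Members of a list can vary together more than random genes do, so these percentiles may look more extreme than they are.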

How the results depend on the processing

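The settings of primary chromosomes, protein-coding genes, no X and Y genes and no shallow libraries were chosen after the data were seen. With a difference of at least 1 on the log2 scale also required, 724 genes were higher and 407 lower in KO than WT, 456 and 240 in Het than WT, 517 and 441 in KO than Het, and 542 departed from the midpoint; the added requirement removes small differences by construction. With an estimated inter-gene correlation, 10 gene lists were called in KO against WT, 3 in Het against WT, 5 in KO against Het and 3 at the midpoint, in place of 23, 11, 13 and 9. Every other setting left the counts of genes within 1.5 times: KO against WT called 5473 genes without WT 3 and KO 1, 5788 to 7924 with single libraries left out, and 8269 with library weights, whose estimation stopped before it converged. It called 5053 of the 10451 genes with a mean of at least 5 FPKM. With only the groups compared in the fit, 5964, 6052 and 7629 genes were called in KO against WT, Het against WT and KO against Het. The main fit, whose spread is shared by all groups, called 7042, 6546 and 6603. H2-K1 reversed in Het against WT on primary chromosomes (0.0342 against -1.39), by construction of the loci summed. Of 715 named gene results called, 672 kept their call and direction wherever they could be tested, the required difference of 1 aside. Of 56 called lists 40 did so, the estimated correlation aside; for the rest the cause was not tested. The replicate numbers paired the samples in part at most: 5 of 10 same-numbered pairs correlated above 0.1 (-0.10 to 0.35) and 3 libraries matched their own number best. The median was 0.086 for same-numbered pairs and -0.018 for the others. Pairs of replicate 4 had 0.259 (WT and Het), 0.352 (WT and KO) and 0.254 (Het and KO), so a factor shared by number is not excluded. With the replicate block 7294, 6993 and 6879 genes were called in KO against WT, Het against WT and KO against Het, and 7022 at the midpoint. FPKM carry no counts, so counting error per gene is unknown.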

Other observations

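The test of genes near Actb and that of X-linked genes were set before their results were seen. Single patterning genes of the list described above differed between the groups: En1 and Shox2, regulators of limb and axial identity, rose in Het (2.09 and 2.09), and Irx1 fell in KO against Het (-2.41). The Wnt antagonist genes Dkk3 and Sfrp1 rose in Het (3.90 and 2.23) and were lower in KO than Het (-4.00 and -3.93).

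Y-linked genes, named after their values were seen, were near 0 in all 11 libraries, with at most 0.269 FPKM for Uty, 0.228 for Eif2s3y and 0.0553 for Ddx3y, and Kdm5d was listed at 0 throughout. Xist lay between 43.99 and 51.5 FPKM in Het and at most 0.0586 elsewhere. Libraries of a group thus did not differ in the state of these genes, which leaves open that they are repeats of the same cell population. In that case the p-values would hold no spread between embryos. If WT cells kept 2 active X chromosomes, unlike Het cells, X-linked genes would be lower in Het, but the median of 559 X-linked genes lay 0.12 above that of 14275 autosomal genes on the log2 scale, which argues against that hypothesis. A single X chromosome in WT and KO cells was not tested.

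DNA carried along with the targeted gene could change its neighbours. Within 5 Mb of Actb, 36.6% of 112 genes were called in KO against WT, at percentile 20.2 of 1000 random windows (median 45.3%), so the neighbours were not called more often than genes elsewhere.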
